A study of Mus musculus with 16 samples.

How the data were processed

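Gene expression was measured by array in mouse embryonic stem cells, which are cultured cells derived from the early embryo. The line was E14tg2a, and per the series' own design text it carried a fusion of the kinase c-Raf that is constitutively active once tamoxifen induces it. In the cell, c-Raf starts the kinase cascade that ends in Erk. Per the labels' protocols the cells were grown on gelatin with serum and LIF, a cytokine that maintains self-renewal, and were treated for 24 hours with 250 nM PD173074, an inhibitor of FGF receptors. They were then stimulated with 250 nM 4-hydroxytamoxifen (4OHT), with the inhibitor still present. The 16 arrays form 8 groups of 2 replicates: DMSO (vehicle only), 0h (inhibitor, not induced), and 30m, 1h, 2h, 4h, 8h and 24h of 4OHT. The description of the 4h samples gives minutes in place of hours, while their title and time point both give 4h, which was used. The labels do not say whether the 2 replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Stem cells exposed to 4OHT without the fusion, to 4OHT without the inhibitor, or to a vehicle for 4OHT were not analysed here.

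Per the file headers, RNA was hybridised in 1 colour (the green channel) to an Agilent mouse array with probe annotation on the mm9 build, and each array was read with Agilent Feature Extraction 11.0.1.1. The labels name Cy5 as the dye, while the scanner files hold a green channel. The scanner files give each spot's processed intensity, which the authors' scanner software had corrected for local background and spatial trends within the array, and its raw median intensity with that of the local background. The authors also deposited a value table, with 1 column per sample. Each of its columns equals the processed intensity of 1 scanner file, rounded to 3 significant digits, on a linear scale with no scaling between arrays and no centring. The column medians ran from 27.3 to 44.7.

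The 2 records of which array belongs to which sample differ. Every scanner file matched exactly 1 value table column at 100% of spots (tolerance 0.6%), and the next best column matched at most 4.99% of spots. For 8 of the 16 arrays, however, the matching column belongs to another sample than the one the scanner file is attached to. The files attached to replicate 2 of DMSO, 0h, 30m and 1h hold the values listed for replicate 1 of 2h, 4h, 8h and 24h, and the reverse. In the value table each of the 2 slides carries 1 replicate of all 8 groups, in time order. In the other record each slide carries both replicates of 4 groups. The results below take each array's sample from the value table and its signals and flags from the scanner file. This choice was made after seeing the data. The counts and list medians with the samples as attached to the scanner files are given with the other alternatives. The fixed analysis plan had assumed, from the attachment and names of the scanner files, that each group lies on 1 slide. Under the value table this does not hold: the slide and the replicate number are the same division of the arrays.

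The signals were analysed as log2 of the processed signal minus the 75th percentile of each array. Control spots and spots flagged as outliers (non-uniform or population outliers, 147 to 240 per array) were left out, and no spot was saturated. Spots of the same probe were averaged. Genes were named by matching each probe's transcript accession, without its version, to a RefSeq table of assembly GRCm38.p6, which was used for names only, so no coordinates are given. Of 55681 probes, 27656 matched 1 gene, 28025 matched none and 0 matched several. A gene was measured by the probe with the highest mean signal over all 16 arrays. It was tested if this probe was well above background on both arrays of at least 1 group, which left 15659 of 20972 genes. Other probes of called genes moved significantly in the opposite direction for 11 of 963 such genes at 24h and for 0 at the other times.

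Depth on an array is signal over background. Between 54.9% and 67.2% of spots were well above background, with 54.9 to 60.0% on slide 1 and 61.5 to 67.2% on slide 2. The 75th percentile of the signal ran from 445 to 660, and the slope of spike-in signal on spike-in amount from 0.979 to 1.024. Correlations between the 2 replicates over genes were 0.982 to 0.990, and no pair of arrays held identical values. The number of arrays, 2 per group, limits the precision. A probe that was not well above background on any array of a group has only a bound there. Such changes are given as "at least" a number of times, from the bright group's mean over the lowest signal well above background on each dim array, or over the probe's own signal where that was higher.

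Differences were tested with limma 3.58.1 (R 4.3.3): 1 fit of 8 group means over all 16 arrays (8 residual degrees of freedom), moderated t statistics from eBayes, and Benjamini-Hochberg adjustment over genes within each comparison. Errors (±) are standard errors of that fit, and a gene is called at an adjusted p under 0.05. Each gene has 1 spread over all 8 groups, so a gap between replicates in 1 group widens its error in every comparison. The comparisons were 0h vs DMSO, each of the 6 times vs 0h, 4h, 8h and 24h vs 2h, and 24h vs DMSO. A set of 26 gene lists, holding 498 genes of which 496 are in the reference, was written before the data were examined. Their names are immediate early, ERK feedback and ETS, growth factor ligands and receptors, naive pluripotency, general pluripotency, primitive endoderm, formative and early epiblast, mesendoderm, trophoblast, neural, two-cell-like, fibroblast and mesenchyme, migration and matrix remodelling, cell cycle, p53 targets, unfolded protein and ATF4 response, heat shock, cholesterol synthesis, glycolysis and hypoxia, interferon response, LIF and STAT3 targets, estrogen receptor targets, ribosome biogenesis, germ cell and imprinted, housekeeping, and c-Raf fusion parts. Each list was tested in the 7 main comparisons with limma's camera (preset inter-gene correlation 0.01, and an estimated correlation as the alternative), and all 182 tests were adjusted together.

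The genes named were chosen by a rule fixed before the data were examined. Per comparison these are the 5 largest rises and the 5 largest falls among called genes with a gene symbol whose arrays do not overlap between the 2 groups, ranked by the fitted change even where the probe has only a bound, and up to 4 called members of each list with the largest change. Always named are Nanog, Pou5f1, Sox2, Klf4, Esrrb, Gata6, Gata4, Sox17, Pdgfra, Egr1, Fos, Dusp6, Spry4, Etv4, Etv5, Fgf5, Otx2, T and Cdx2, with Esr1 in every array.

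The labels give every group the replicate numbers 1 and 2. The deviations of the replicate 1 arrays from their group means correlated over genes at 0.33 to 0.66 in all 28 pairs of groups, so the numbers pair the samples, as the shared slide does in the value table. The planned fit has no block, and every ± is from it, also beside an adjusted p with the block. The count with the replicate number as a block, which is also the slide as a block, is given beside the printed counts of genes called in a comparison and of list members called that it moves by over 1.5 times, and differences within replicate 1 and within replicate 2 are differences within a slide.

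The alternatives were normexp background correction of the median signals (the files hold no mean signal; offset 50), quantile normalization, median centring, no filter on dim probes, a filter on all 16 arrays, the replicate block, eBayes with trend and robust settings, a fit of only the 2 groups compared, the mean of a gene's probes, the value table's rounded values, a 2-fold minimum, and leaving out each array. A fit of only 2 groups has fewer residual degrees of freedom than the 8 of the full fit, so it can call fewer genes for that reason alone. The planned fit of only the 8 arrays of a slide was not run, since a slide holds 1 array per group in the value table. Added after seeing the data were the samples as attached to the scanner files, the 8 arrays on which both records agree, and the block together with a 2-fold minimum.

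The fit was tested on simulated arrays with the real genes' means and spreads (15627 genes, 10 runs, 200 genes changed per run in 24h vs 0h). It called 43.4% of genes changed by 1 on the log2 scale, 78.8% of those changed by 2 and 94.8% of those changed by 4, and 5.8% of its calls fell on unchanged genes. The simulated arrays had independent errors without the shift that the samples of a slide share, so these rates hold only for that case. A list of 20 genes shifted by 1 was called in 10 of 10 runs and an unshifted list in 0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.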

Results

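The data hold 16 arrays of mouse embryonic stem cells in 8 groups of 2 replicates, and 15659 genes were tested. They follow cells with an inducible c-Raf fusion from an FGF receptor block (0h) through 30m, 1h, 2h, 4h, 8h and 24h of stimulation with 4OHT, with vehicle-treated cells (DMSO) beside them. The series describes this as a time course of Erk stimulation. Log2 values are scaled to each array's 75th percentile, n = 2 arrays per group throughout, and array identities follow the value table, which differs from the scanner files' record for 8 arrays. This choice was made after the data were seen, and the results rest on it: with arrays grouped as attached to the scanner files, 24h vs 0h had 331 called genes in place of 3709, 0h vs DMSO had 6 in place of 548 and 2h vs 0h had 560 in place of 18.

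The first comparison, 0h vs DMSO, asks what 24 hours of PD173074 did to unstimulated cells. Feedback genes of Erk signalling were in part lower with the inhibitor, while immediate early genes, another Erk-driven set, were not shifted as a list (0 of 29 called, 1 higher and 2 lower with the replicate block, median 0.07, camera adjusted p = 0.91; Egr1 at 0.50 ± 0.57). Spry4, a feedback inhibitor of receptor signalling, fell by 3.40 ± 0.38 on the log2 scale (limma adjusted p = 0.0033), which is 10.5-fold. Etv1, an ETS transcription factor, fell by 2.13 ± 0.34 and Dusp2, a phosphatase that acts on Erk, fell by 1.65 ± 0.30. Spred3, another feedback inhibitor, was at least 2.47-fold lower (adjusted p = 0.0036).

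In the list of ERK feedback and ETS genes, 4 of 20 measured members fell, 0 rose and 16 were not called (11 fell adjusted over the list alone, and 10 with the replicate block). The median change of the list was -0.91, or -0.71 with members below background at their bound, and -0.78 and -1.24 within the slides of replicate 1 and replicate 2. The camera adjusted p was 4.54e-09, against an adjusted p = 0.708 with an estimated correlation. Etv4 and Dusp6 had changes of -3.01 ± 0.74 and -1.87 ± 0.59 and were called only with the replicate block (adjusted p = 0.00043 and 0.0016, against 0.0564 and 0.124). Etv5 was at -0.36 ± 0.31.

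Of the list of formative and early epiblast genes, which mark the step after naive pluripotency, 2 of 16 members fell (7 with the block): Pou3f1, a POU-domain transcription factor, by 2.54 ± 0.49 and the kinase gene Pim2 by 2.60 ± 0.37. The list's median was -1.01 (camera adjusted p = 0.00015, adjusted p = 0.712 with an estimated correlation). The naive pluripotency list had a median of 0.60 (camera adjusted p = 0.0361, adjusted p = 0.93 with an estimated correlation and 0.0699 with the replicate block), with 0 of 22 members called (2 higher and 1 lower with the block). Nanog was at 1.35 ± 0.80, Klf4 at 0.84 ± 0.58, Esrrb at 0.31 ± 0.37, Sox2 at 0.45 ± 0.14 and Pou5f1 at -0.36 ± 0.35, all not called. Sox2 was called with the block (adjusted p = 0.0371). In every comparison the error of Nanog also holds the gap between its 2 arrays at 24h (-1.76 and 1.57). Its arrays stood at 3.41 and 2.97 in DMSO and at 4.48 and 4.59 at 0h. The lack of a call thus does not show that Nanog stayed level.

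A few primitive endoderm markers were higher with the inhibitor. Lama1, a laminin chain, rose by 1.61 ± 0.19, Col4a1, a collagen chain, by 1.23 ± 0.26 and Sparc by 0.76 ± 0.17, which makes 3 of 31 members of that list, or 8 higher and 1 lower with the block (median 0.47, camera adjusted p = 0.00067, adjusted p = 0.415 with an estimated correlation). The transcription factors of this lineage were not called, with Gata6 at -0.83 ± 0.54, Gata4 at 0.57 ± 0.52 and Sox17 at -0.17 ± 0.38. Genes of the gastrulating embryo went both ways: Gsc rose at least 7.64-fold and Wnt3 at least 1.91-fold, while Wnt8a was at least 3.70-fold lower. Single called members of other lists were Cdkn1b, a cell cycle inhibitor (0.83 ± 0.12), Timp1, an inhibitor of matrix proteases (0.86 ± 0.13), Col5a1 (0.77 ± 0.13), B2m (0.77 ± 0.15), Bst2, an interferon-response gene (-1.85 ± 0.28), Dlk1 (-1.03 ± 0.17) and Snrpn (-0.98 ± 0.12). Ribosome biogenesis genes had a median of -0.28 with 0 of 22 called, and 7 lower with the block (camera adjusted p = 0.00054, adjusted p = 0.93 with an estimated correlation). The housekeeping list had a median of -0.17, with -0.23 and 0.01 within the 2 slides.

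Over all genes, 347 were higher and 201 lower with the inhibitor. Ranked by fitted change, which for probes below background can exceed the bound, the 5 top rises were those of Lrrc15 (5.50 ± 0.69), Gsc, Lpar3 (at least 5.88-fold), Calcoco2 (4.28 ± 0.86) and Hesx1, a homeobox gene (3.96 ± 0.93). The 5 top falls by the same rank were those of Col6a5 (at least 4.16-fold), Prss44 (at least 6.27-fold), Spry4, Wt1 (-3.34 ± 0.40) and Vrtn (-3.33 ± 0.56). The replicate block raised the count to 1293 higher and 1049 lower, median centring gave 228 higher and 33 lower, and a fit of only these 2 groups called 0 genes (2777 at an unadjusted p under 0.05 in the full fit). Leaving out 1 array gave 72 (DMSO replicate 1), 195 (DMSO replicate 2), 101 (0h replicate 1) or 85 genes (0h replicate 2).

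**Figure D1:**
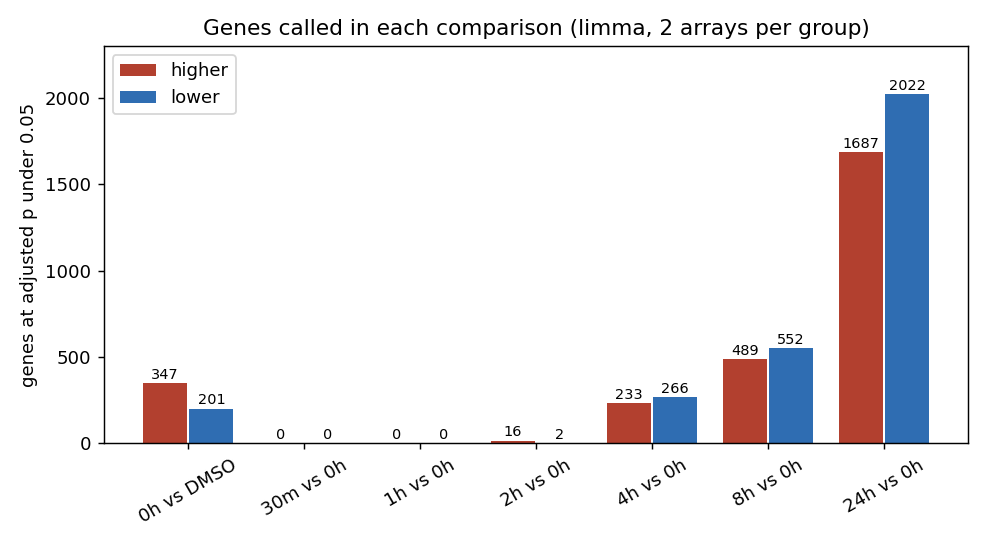
Number of genes called higher (red) and lower (blue) at an adjusted p under 0.05 on the y axis, for each of the 7 main comparisons on the x axis, from 1 limma fit with 2 arrays per group. Counts vs 0h grow from 0 at 30m and 1h to 1687 higher and 2022 lower at 24h.

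The next comparisons set each time of 4OHT against 0h and ask how the cells respond to the stimulated c-Raf fusion. In the first hour some immediate early genes, which cells switch on without making new protein, moved by 1h. At 1h Egr1 stood 3.77 ± 0.57 and Fos 3.55 ± 0.46 above 0h on the log2 scale, both transcription factors of this class. Over all genes neither was called (limma adjusted p = 0.404 and 0.231). With the replicate block 3 genes were called: Egr1, Fos and Egr2 (at least 6.51-fold higher, adjusted p = 0.0261). In the immediate early list, 5 of 29 members rose when adjusted over the list alone, namely Fos, Egr1, Egr2, Ccn1 (0.77 ± 0.17) and Zfp36 (1.20 ± 0.31), and 0 over all genes. The list's median was 0.23, and 0.25 and 0.16 within the 2 slides (camera adjusted p = 9.13e-08, adjusted p = 0.788 with an estimated correlation).

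At 1h the ERK feedback and ETS list had a median of 0.25 with 0 of 20 called (camera adjusted p = 0.0288, adjusted p = 0.93 with an estimated correlation). Without 1h replicate 1 or 0h replicate 2 that median was 0.068 or 0.075 and the list was not called. Its Spry4 stood at 1.42 ± 0.38 and Dusp6 at 1.05 ± 0.59. The cholesterol synthesis list had a median of 0.12 (camera adjusted p = 0.0012, adjusted p = 0.788 with an estimated correlation) and the glycolysis and hypoxia list one of -0.06 (camera adjusted p = 0.0452, adjusted p = 0.93 with an estimated correlation, 0.0789 with the block). At 30m Egr1 stood at 0.95 ± 0.57 and Fos at 0.68 ± 0.46. Limma called 0 genes at 30m and at 1h, with 96 and 345 genes at an unadjusted p under 0.05. Without 30m replicate 2, 21 genes were called at 30m, and without 0h replicate 2, 9 were called at each of these times.

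At 2h, 16 genes were higher and 2 lower than at 0h. Among transcription factors of the immediate early class, Egr1 rose by 5.38 ± 0.57 (adjusted p = 0.0079), which is 41.7-fold, Fos by 4.85 ± 0.46 and Jun by 2.71 ± 0.35, and Egr2 rose at least 26.6-fold. The mRNA-destabilising genes Zfp36 and Zfp36l1 rose by 2.41 ± 0.31 and 1.74 ± 0.26, and Ccn1 by 1.22 ± 0.17. Feedback genes were higher too, with Spry4 up by 4.39 ± 0.38, Phlda1 by 3.90 ± 0.47 and Dusp2 by 2.58 ± 0.30. The prostaglandin genes Ptgs2, a cyclooxygenase, and Ptger2, a receptor, rose at least 12.7-fold and by 2.45 ± 0.23. Lor rose by 4.39 ± 0.61, Slc39a14 by 1.80 ± 0.27, Adipoq at least 3.52-fold and Taf1d by 0.74 ± 0.10. The lower genes were Fam43b (at least 1.57-fold) and Cend1 (at least 1.76-fold).

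As lists at 2h, 6 of 29 immediate early members rose (median 0.52, camera adjusted p = 2.41e-15) and 3 of 20 ERK feedback and ETS members rose, or 7 with the block (median 0.94, camera adjusted p = 7.89e-13). Cholesterol synthesis shifted by a median of 0.31 with 0 of 20 called, and 2 with the block (camera adjusted p = 8.36e-10). All 3 had an adjusted p = 0.415 with an estimated correlation. Heat shock and ribosome biogenesis had medians of 0.12 and 0.18 with 0 called (camera adjusted p = 0.0419 and 0.0487, adjusted p = 0.93 for both with an estimated correlation). The housekeeping list stood at a median of 0.10, so a shift near that of heat shock was not particular to it. Dusp6 stood at 2.63 ± 0.59 and was called only with the block (adjusted p = 0.0022). The always named markers of pluripotency were not called, with Nanog at -0.10 ± 0.80, Klf4 at -0.07 ± 0.58, Esrrb at 0.00 ± 0.37, Pou5f1 at 0.36 ± 0.35 and Sox2 at 0.22 ± 0.14. The block raised the count at 2h to 59 higher and 16 lower. Median centring gave 5 higher and 0 lower, no filter on dim probes 11 genes and a fit of only these 2 groups 0. The balance turned without 0h replicate 2, where more genes were called lower than higher. Leaving out 0h replicate 1 gave 2 genes and leaving out 2h replicate 1 gave 11.

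At 4h, 233 genes were higher and 266 lower than at 0h, though the direct comparison with 2h called 1 gene (88 with the block). Cdx2, a homeobox gene of trophectoderm and posterior mesoderm, was at least 30.1-fold higher (adjusted p = 0.0054), Evx1, a homeobox gene of the primitive streak, rose by 3.83 ± 0.54, Hand1 by 1.87 ± 0.30, and Twist1, a mesenchymal transcription factor, by 4.25 ± 0.64. The feedback list stood at 10 of 20 higher and 0 lower (median 1.95, camera adjusted p = 2.41e-15, adjusted p = 0.415 with an estimated correlation), led by Phlda1 (5.91 ± 0.47), Dusp4 (5.11 ± 0.71), Spry4 (4.89 ± 0.38) and Dusp2 (4.25 ± 0.30), and Dusp6 rose by 3.40 ± 0.59. Etv4 at 2.40 ± 0.74 and Etv5 at 0.74 ± 0.31 were called only with the block (adjusted p = 0.0017 and 0.0067).

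Of the immediate early list at 4h, 10 of 29 were higher and 1 lower (17 and 2 with the block), with Egr1 at 5.18 ± 0.57, Fos at 4.63 ± 0.46, Arc at 3.54 ± 0.63 and Egr2 at least 18.8-fold higher (camera adjusted p = 8.36e-10, adjusted p = 0.712 with an estimated correlation). Cholesterol synthesis genes were higher as a list, with 3 of 20 called over all genes and 12 adjusted over the list alone or with the block: Sc5d by 0.91 ± 0.18, Hmgcs1, which makes an early precursor of sterols, by 0.75 ± 0.13 and Lss by 0.67 ± 0.16 (median 0.52, camera adjusted p = 7.78e-10, adjusted p = 0.415 with an estimated correlation). Ribosome biogenesis genes had a median of 0.38 with 0 of 22 called, and 12 called with the block (camera adjusted p = 1.27e-05, adjusted p = 0.853 with an estimated correlation). General pluripotency genes had a median of 0.35, with 7 of 17 higher with the block (camera adjusted p = 0.0131, adjusted p = 0.93 with an estimated correlation). The housekeeping list also stood higher at 4h, with a median of 0.19, so a small upward shift was not particular to these lists. Other called list members included Hbegf, an EGF-family ligand (2.63 ± 0.57), Plaur, the urokinase receptor (3.09 ± 0.60), Ccnd2, a cyclin (3.06 ± 0.52), Xbp1 (0.81 ± 0.19), Pax6 (1.17 ± 0.27), Timp1 (0.73 ± 0.13), Rara, a retinoic acid receptor (-0.55 ± 0.11), and Ndrg1 (-1.51 ± 0.15).

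The 5 top rises at 4h by fitted change were those of Phlda1, Cdx2, Lor (5.62 ± 0.61), Ptgs2 (at least 34.7-fold) and Egr1. The 5 top falls by fitted change, most of them below background and shown only to small bounds, were those of Aoc3 (-2.60 ± 0.49), Matn1 (at least 1.40-fold), Wnt3 (at least 1.88-fold), Ppp1r3c (at least 1.33-fold) and Pdgfrb, a growth factor receptor (at least 3.23-fold). Ppp1r3c had a value of 0.02 after normexp background correction. The naive pluripotency list had 0 of 22 called, and 5 higher with the block, with Nanog at -0.96 ± 0.80 and Klf4 at -0.59 ± 0.58 not called in either fit. The block gave 1214 higher and 1309 lower genes at 4h, median centring 69 higher and 35 lower, and a fit of only these 2 groups 6 genes. Leaving out 1 array gave 43 (0h replicate 1), 102 (0h replicate 2) or 41 genes (4h replicate 1). The balance of rises and falls turned with some settings: 32 higher and 11 lower without 0h replicate 1, 31 and 10 without 4h replicate 1, and 170 and 119 with a 2-fold minimum.

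At 8h, 489 genes were higher and 552 lower. Single mesendoderm and trophoblast genes were higher, while neither list passed as a whole: Cdx2 at least 27.4-fold, Hand1 by 2.93 ± 0.30, Evx1 by 2.79 ± 0.54, Mesp1, a gene of early mesoderm, at least 1.90-fold, and Tead4 by 1.91 ± 0.41. In the mesendoderm list 6 of 18 members rose and 1 fell, Wnt3, which was at least 2.12-fold lower (7 and 4 with the block, camera adjusted p = 0.175). Of 14 trophoblast genes 3 rose (3 higher and 2 lower with the block, camera adjusted p = 0.15). Of the formative and early epiblast list 2 of 16 rose (6 higher and 1 lower with the block), Pou3f1 by 2.73 ± 0.49 and Dnmt3a, a DNA methyltransferase, by 0.78 ± 0.15 (median 0.83, camera adjusted p = 0.0032, adjusted p = 0.788 with an estimated correlation).

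Fgf5, Otx2 and T, markers of the epiblast and primitive streak, stood at 2.07 ± 0.66, 0.88 ± 0.34 and at least 2.68-fold higher at 8h and were called only with the block (adjusted p = 0.0034, 0.0073 and 0.0057). Against 2h, T was called, at least 2.23-fold higher at 8h (adjusted p = 0.0309). Gbx2, a homeobox gene downstream of LIF, rose by 3.40 ± 0.75 and was the 1 called of 22 naive pluripotency genes (2 higher and 2 lower with the block). Nanog stood at -1.62 ± 0.80, Klf4 at -1.79 ± 0.58 and Esrrb at -0.59 ± 0.37. Growth factor genes went both ways, with 4 higher and 2 lower of 18 (4 and 6 with the block): Bmp4 rose by 3.30 ± 0.76, Hbegf by 2.41 ± 0.57 and Areg at least 1.75-fold, while Fgf3 was at least 2.11-fold lower.

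Genes of migration and matrix remodelling were higher at 8h in 4 of 19 cases (6 higher and 2 lower with the block): the protease Mmp9 at least 6.57-fold, Plaur by 3.20 ± 0.60, Hmga2 by 2.55 ± 0.56 and Itgb1, an integrin, by 1.54 ± 0.36 (median 0.09, camera adjusted p = 0.0452, adjusted p = 0.415 with an estimated correlation). Thy1 and Twist1 rose by 2.54 ± 0.21 and 2.51 ± 0.64, Cdh2, N-cadherin, by 2.00 ± 0.31, Ccnd2 by 2.60 ± 0.52, Junb by 2.29 ± 0.53, Ddx58 by 2.09 ± 0.36, Krt18 by 1.81 ± 0.30 and Perp by 1.48 ± 0.33. Falls included Hspa5, the main chaperone of the endoplasmic reticulum (-0.78 ± 0.15), Cdkn1b (-0.66 ± 0.12), Hhex (-0.68 ± 0.17), Socs1 (-0.68 ± 0.16) and Map2 (-0.86 ± 0.21). ERK feedback and ETS genes were higher in 12 of 20 cases (median 2.07, camera adjusted p = 8.46e-16, adjusted p = 0.415 with an estimated correlation), with Etv4 by 3.67 ± 0.74. The immediate early list stood at 11 of 29 higher and 0 lower (14 and 1 with the block), with Egr1 at 4.31 ± 0.57, Fos at 3.45 ± 0.46 and Fosl1 at 3.22 ± 0.59 (camera adjusted p = 6.82e-07, adjusted p = 0.788 with an estimated correlation). Cholesterol synthesis and ribosome biogenesis had medians of 0.28 and 0.24 with 0 called in each, and 4 and 8 higher with the block (camera adjusted p = 0.00032 and 0.00043, adjusted p = 0.788 and 0.93 with an estimated correlation). The housekeeping median was 0.08.

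The 5 top rises at 8h by fitted change were those of Aldh1a3, which makes retinoic acid (at least 71.6-fold), Grm6 (at least 23.0-fold), Vgf (6.06 ± 0.47), Col6a5 (at least 16.7-fold) and Cdx2. The 5 top falls were those of Bhmt2 (-3.29 ± 0.63), Lpar3 (-3.28 ± 0.81), Rarres1 (at least 3.75-fold), Hhip, a hedgehog antagonist (-3.19 ± 0.55) and Bmpr1b, a BMP receptor (-2.98 ± 0.57). The block gave 1321 higher and 1972 lower genes, median centring 250 and 226, and a fit of only these 2 groups called 0. Leaving out 1 array gave 179 (0h replicate 1), 371 (0h replicate 2), 152 (8h replicate 1) or 1917 genes (8h replicate 2). The balance turned to 146 higher and 33 lower without 0h replicate 1, 116 and 36 without 8h replicate 1, and 410 and 281 with a 2-fold minimum.

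At 24h, 1687 genes were higher and 2022 lower than at 0h. The naive pluripotency network was largely lower: 14 of 22 members fell and 1 rose (14 and 2 with the replicate block). Nanog fell by 4.63 ± 0.80 (adjusted p = 0.0025), which is 24.8-fold, Prdm14 by 4.65 ± 0.86, Klf4 by 3.46 ± 0.58, Tfcp2l1 by 2.36 ± 0.65, Esrrb by 2.00 ± 0.37 and Spp1 by 3.81 ± 0.47, while Gbx2 rose by 4.58 ± 0.75. The list's median was -2.14, with -2.88 in replicate 1 and -1.41 in replicate 2 (camera adjusted p = 1.87e-05, adjusted p = 0.788 with an estimated correlation). Without 24h replicate 1 the median was -1.33. Nanog itself was at -6.24 in replicate 1 and -3.02 in replicate 2.

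Pou5f1 and Sox2, core factors that formative cells keep, were not called at 24h, with 0.60 ± 0.35 and -0.34 ± 0.14 (Sox2 adjusted p = 0.0476 with the block). Of the general pluripotency list 3 of 17 rose and 5 fell (5 and 6 with the block). Among them Utf1 rose by 1.78 ± 0.42 and Dppa2 by 1.24 ± 0.38, while Gdf3, a TGF-beta family ligand, fell by 1.39 ± 0.15. Formative and early epiblast genes split, with 3 higher and 4 lower of 16 (5 and 4 with the block, median 0.51, camera adjusted p = 0.595). Pou3f1 rose by 3.49 ± 0.49, and Zic2 fell by 3.89 ± 1.16, Zic5 by 2.96 ± 0.78 and Sall2 by 2.23 ± 0.43. Fgf5 and Otx2 stood at 0.23 ± 0.66 and 0.04 ± 0.34, not called, and T was below background at both 0h and 24h.

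Primitive endoderm markers changed in part. Gata6, the transcription factor that opens this lineage, rose by 4.77 ± 0.54 (adjusted p = 0.00031), which is 27.2-fold, and Pdgfra, a surface receptor of the lineage, was at least 2.71-fold higher. Krt19 and Krt18 rose by 3.30 ± 0.28 and 2.75 ± 0.30 and Lrp2 by 1.93 ± 0.56. In all 7 of 31 members rose and 3 fell (8 and 5 with the block, median 0.11, camera adjusted p = 0.47). That median was -0.15 without 0h replicate 1 and -0.003 without 24h replicate 1. Gata4 and Sox17, which act after Gata6, were not called, at -0.24 ± 0.52 and 0.84 ± 0.38.

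Single mesendoderm genes went both ways at 24h. Lefty1 and Lefty2, Nodal antagonists, fell by 5.52 ± 1.31 and 4.96 ± 0.86, Cfc1, a Nodal co-receptor, by 6.34 ± 1.20, and Gsc was at least 6.06-fold lower. Hand1 rose by 4.64 ± 0.30, and the mesendoderm list held 5 higher and 4 lower of 18 members (camera adjusted p = 0.656). Of 14 trophoblast markers 3 rose and 1 fell (6 and 4 with the block): Cdx2 was at least 12.3-fold higher, Krt7 rose by 2.85 ± 0.28, and Gata2 fell by 3.18 ± 0.67 (camera adjusted p = 0.402). Of 12 neural markers 1 rose and 4 fell: Cdh2 rose by 2.63 ± 0.31, Tubb3 fell by 2.80 ± 0.40, Pax6 by 2.10 ± 0.27 and Zbtb16 by 0.97 ± 0.22 (camera adjusted p = 0.26).

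Mesenchymal and invasion genes moved both ways. Mmp9 was at least 23.6-fold higher, Hmga2 rose by 3.65 ± 0.56, Twist1 by 3.38 ± 0.64 and Thy1 by 2.34 ± 0.21, while Zeb1 fell by 3.58 ± 0.62, Lamb3 by 3.87 ± 0.74, Vim, vimentin, by 2.20 ± 0.37 and Fn1, fibronectin, by 1.07 ± 0.21. The migration and matrix list had 4 of 19 higher and 4 lower, and the fibroblast and mesenchyme list 2 of 13 higher and 3 lower. In the growth factor list, Fgfr4 rose by 5.84 ± 0.37, Bmp4 by 2.68 ± 0.76 and Areg at least 2.12-fold, while Igf1 was at least 8.39-fold lower. Cell cycle inhibitors Cdkn2b and Cdkn2a rose by 2.10 ± 0.44 and 1.26 ± 0.41, beside Cdk6 (1.66 ± 0.39) and Ccnd2 (1.69 ± 0.52). That list counted 4 of 24 higher and 3 lower (5 and 9 with the block).

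Many feedback genes and part of the immediate early genes were higher at 24h than at 0h. ERK feedback and ETS genes were higher in 14 of 20 cases and lower in 0 (median 2.57, camera adjusted p = 2.31e-09, adjusted p = 0.708 with an estimated correlation), with Phlda1 at 6.16 ± 0.47, Dusp4 at 5.67 ± 0.71, Dusp2 at 5.02 ± 0.30, Etv4 at 4.97 ± 0.74, Spry4 at 4.94 ± 0.38 and Dusp6 at 3.97 ± 0.59. Etv5 stood at 0.10 ± 0.31. Of 29 immediate early genes 13 were higher and 1 lower (20 and 1 with the block), with Egr1 at 3.78 ± 0.57, Myc at 3.84 ± 0.60, Fosl1 at 3.68 ± 0.59, Fos at 2.71 ± 0.46 and Egr2 at least 12.9-fold higher (camera adjusted p = 4.65e-06, adjusted p = 0.788 with an estimated correlation).

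The 5 top rises at 24h by fitted change were those of Krt23 (at least 105-fold), Aldh1a3 (at least 165-fold), Grm6 (at least 97.8-fold), Col6a5 (at least 60.4-fold) and Baalc (at least 52.5-fold). The 5 top falls were those of Cfc1, Lrrc15 (at least 41.2-fold), Sfrp1, a Wnt antagonist (-5.84 ± 1.07), Cdhr1 (-5.71 ± 1.05) and Spic (-5.71 ± 0.90). The block gave 2872 higher and 3309 lower genes, median centring 797 and 1351, and a fit of only these 2 groups called 1759. Leaving out 1 array gave 2221 (0h replicate 1), 2256 (0h replicate 2) or 1859 genes (24h replicate 1).

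**Figure D2:**
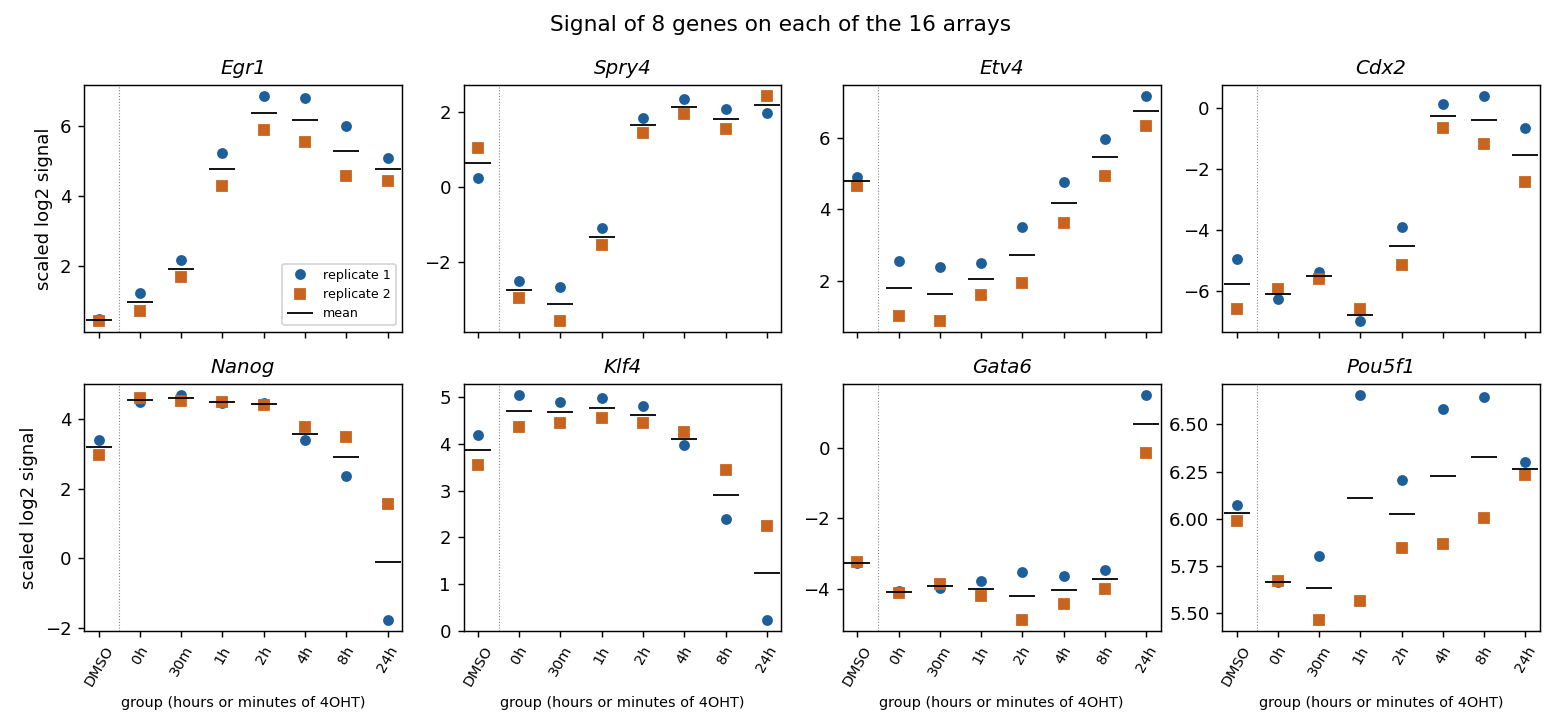
Scaled log2 signal (y axis) of 8 genes in each of the 8 groups (x axis), with replicate 1 as blue circles, replicate 2 as orange squares and their mean as a black bar. Egr1 and Spry4 rise by 2h, Cdx2 by 4h and Gata6 at 24h, where Nanog falls to -1.76 in replicate 1 and 1.57 in replicate 2, while Pou5f1 stays between 5.47 and 6.65 on all arrays.

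Part of the genes called at one time were called at the next. Of the 18 genes called at 2h, 16 were called at 4h, all in the same direction (0.6 for independent lists). Of 499 genes called at 4h, 229 were called at 8h, all in the same direction (33.2 for independent lists), and 287 at 24h, 255 in the same direction and 32 in the opposite one (118.2). Of 1041 called at 8h, 818 were called at 24h, 804 of them in the same direction (246.6). These comparisons share the 0h arrays, which can by itself raise such overlaps above those of independent lists, so the counts do not measure how far the changes lasted. Genes first called at 24h numbered 2794, against 812 first called at 8h and 483 at 4h. A moderated F test over the 6 times called 3332 genes, and 7144 with the block.

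Against 2h of 4OHT, with no 0h array in the comparison, 4h differed in 1 gene (Cyth4, 3.19 ± 0.33, named after its value was seen), 8h in 813 and 24h in 3618. With the block these counts were 88, 2895 and 6126, and in fits of only the 2 groups 0, 1 and 1536. For 8h vs 2h the split was 429 higher and 384 lower, against 223 and 57 after median centring, 1190 and 1705 with the block and 337 and 169 with a 2-fold minimum. At 8h Jun, already past its early rise, was lower than at 2h by 2.75 ± 0.35 and Ccn2 by 1.13 ± 0.23, while Fosl2 was higher by 2.52 ± 0.54 and Dnmt3a by 1.28 ± 0.15. Aldh1a3 rose by 6.05 ± 0.45, Esam by 4.99 ± 0.34 and Btbd17 by 4.80 ± 0.40, and the homeobox gene Six2 was at least 10.8-fold lower. At 24h Nanog was lower than at 2h by 4.53 ± 0.80, Zic2 by 5.90 ± 1.16 and Sox2 by 0.56 ± 0.14, Gata6 was higher by 4.86 ± 0.54, and Fos had dropped by 2.15 ± 0.46. Leaving out 1 array moved 8h vs 2h to between 118 genes (8h replicate 1) and 1531 (8h replicate 2), with 139 without 2h replicate 1 and 202 without 2h replicate 2. The higher and lower genes were then 95 and 23 without 8h replicate 1, 110 and 29 without 2h replicate 1, and 129 and 73 without 2h replicate 2. For 24h vs 2h it gave 2239 (2h replicate 1), 2370 (2h replicate 2) or 1837 genes (24h replicate 1).

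**Figure D3:**
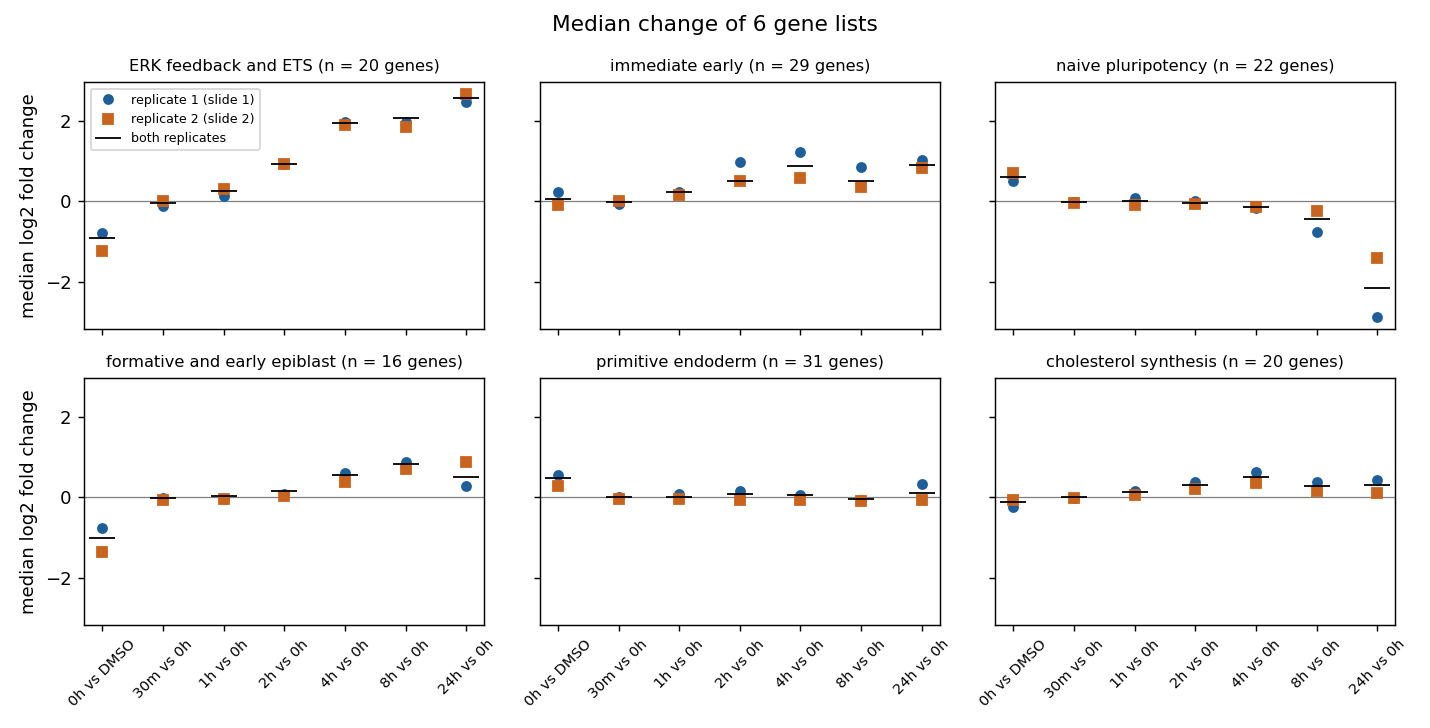
Median log2 fold change (y axis) of 6 gene lists in each of the 7 main comparisons (x axis), within replicate 1 (blue circles), within replicate 2 (orange squares) and over both (black bars). The ERK feedback and ETS list goes from -0.91 in 0h vs DMSO to 2.57 at 24h, and the naive pluripotency list from 0.60 to -2.14.

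The comparison of 24h with DMSO asks whether stimulated cells under the inhibitor differ from cells that never met it. They did, in 1027 genes higher and 751 lower. Egr1 was higher than in DMSO by 4.28 ± 0.57, Phlda1 by 5.36 ± 0.47, Spry4 by 1.55 ± 0.38, Gata6 by 3.93 ± 0.54 and Hand1 by 3.84 ± 0.30, and Aldh1a3 was at least 139-fold higher. Nanog was lower by 3.29 ± 0.80, Klf4 by 2.63 ± 0.58, Esrrb by 1.69 ± 0.37 and Lefty1 by 4.80 ± 1.31. The block gave 1964 higher and 2103 lower genes and a fit of only these 2 groups 185, and without DMSO replicate 1, DMSO replicate 2 or 24h replicate 1 the count was 442 (344 higher, 98 lower), 1026 or 356 (272 higher, 84 lower).

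Genes that the inhibitor had changed were compared with those changed by 24h of 4OHT. Of 201 genes lowered by the inhibitor, 166 were higher at 24h than at 0h, where independent lists would share 21.7. Of 347 raised by it, 270 were lower at 24h, against 44.8. Spry4, Etv1 and Dusp2 are among the genes lowered by the inhibitor, and Lrrc15 and Gsc among those raised. Same-direction calls numbered 0 and 4. Both comparisons use the 0h arrays. Unchanged simulated groups sharing such arrays gave 0.02 opposite calls on average. With no changed genes such groups give few calls of any kind, so that count cannot show what the shared arrays add. The covariance of the 2 sets of fold changes over genes was -0.33, against -0.04 in simulated unchanged groups. Their correlation was -0.62, against -0.50 in those simulated groups. With no changed genes the shared arrays alone give that -0.50, so it cannot show how much they add where genes change. The comparison 24h vs 2h shares no array with 0h vs DMSO. In it 159 of the lowered genes were higher (21.5 for independent lists) and 249 of the raised genes were lower (43.1). The covariance was -0.27 and the correlation -0.53. With the block 1801 genes were called in opposite directions in 0h vs DMSO and 24h vs 0h, against 436 without it, 216 with median centring, 237 with a 2-fold minimum, 274 with no filter on dim probes and 0 with arrays grouped as attached to the scanner files. Leaving out any 1 array of DMSO or 0h lowered the 436 sharply, while leaving out a 24h array lowered it slightly.

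Esr1, the estrogen receptor gene whose ligand-binding part tamoxifen-inducible fusions commonly carry, lay between -4.66 and -1.98 on the scaled log2 axis. It was well above background on all arrays, and was called with the block at 4h (1.61 ± 0.75, adjusted p = 0.0157) and 8h (1.29 ± 0.75, adjusted p = 0.0277). At 0h it stood at -4.33 and -4.56, where the lowest signals well above background were -5.07 and -5.30. In DMSO it stood at -3.04 and -4.66, against -2.93 and -3.38 at 8h. Braf, a kinase gene of the list of c-Raf fusion parts, rose by 1.11 ± 0.34 at 24h.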

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

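The tests of the inhibitor's shared arrays, of the Spry4 change, of array identity with slide means removed and of the genes beyond the DMSO level with 1 array left out were chosen only after the result was seen.

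Some genes were called in opposite directions at 2 times vs 0h, with at least a 2-fold fitted change at both and a called difference between the times (limma). In all, 48 such pairs of times in 41 genes had opposite calls at any size. The homeobox genes Pax6 and Meis2 were higher at 4h and lower at 24h, with differences of -3.28 and -2.35 on the log2 scale, as was Rnd1, a small GTPase (-2.75), and Zfp287 was lower at 4h and higher at 24h (2.71). For 6 more genes the lower side was below background, so their fitted differences are uncertain and a 2-fold fall is not shown. Serpinb1b rose by 3.67 at 4h (fitted differences of 24h from 4h and 8h of -5.59 and -3.91), with no fall at 24h supported by its bound. Wif1 (-4.30 and -3.88) was at least 1.90-fold lower at 24h. Fam43b (2.94) was at least 1.57-fold lower at 2h, Cyp4f41-ps (2.59) at least 1.27-fold lower at 4h, and Glipr1l1 (3.50) and Plcd4 (2.99) at least 1.17-fold and 1.27-fold lower at 8h.

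Probes without a gene name were outside the comparisons above. Of 14512 such probes above background, 705 were called in 24h vs 0h, 368 higher and 337 lower (1730 with the replicate block).

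The pattern that bears on every value is that 8 arrays belong to one sample in the scanner files' record and to another in the value table. Each group keeps 1 array on which both records agree, so the disputed arrays were set against those 8. Of the 8 disputed arrays, 3 correlated best with the agreed array of their value table group and 0 with that of their scanner record group. Between those 2 groups alone, with no bound written beforehand, 7 of the 8 correlated more highly with the value table group. For the value table's 24h replicate 1 the correlations were 0.782 with that group and -0.443 with the scanner record group. The exception was 0h replicate 2, at 0.235 and 0.242. The 0 argues against value table columns headed with the wrong samples, which needed at least 6 (bound against it: at most 2), although each disputed array shares its slide with the agreed array of its scanner record group. By the bounds written beforehand, scanner files attached to the wrong samples stays open, since 3 lies between 2 and 6. With each gene's slide mean removed, a version chosen after that result, 6 correlated best with their value table group, but this version is void: the centring lowers correlations within a slide, and so those with the scanner record group. The submitters' own key was not used here.

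A second pattern is the smaller change of Nanog, Klf4 and Gata6 in replicate 2 at 24h: Nanog changed by -6.24 and -3.02, Klf4 by -4.81 and -2.12, and Gata6 by 5.56 and 3.97. Smaller changes in replicate 2 were not limited to 24h. The naive pluripotency median at 8h was -0.77 in replicate 1 and -0.23 in replicate 2, and the immediate early median at 4h was 1.23 and 0.58. At 24h the ERK feedback and ETS median went the other way, with 2.46 and 2.68. Over the genes called, the slope of replicate 2 on replicate 1 was 0.836 (0.821 to 0.855) for rises and 0.743 (0.719 to 0.764) for falls. The ranges come from resampling genes within these arrays, so they do not measure the spread between arrays or cultures. These slopes alone neither meet nor exclude compressed signals on the replicate 2 array of 24h. An even compression of all signals is argued against by Spry4, a gene picked after its value was seen. Spry4 rose by 5.40 in replicate 2 and 4.48 in replicate 1, and stood at 2.43 and 1.98 at 24h. Dusp6 also rose more in replicate 2 (4.30 and 3.63), but from a lower 0h level (1.43 and 2.65). At 24h Dusp6 was lower in replicate 2 (5.73 and 6.28), so its rise does not bear on compression of that array. The spike-in slope of that array, 0.979, was the lowest of all arrays, against 0.9998 for 24h replicate 1. These 2 arrays lie on different slides. Slopes ran from 0.979 to 0.992 on slide 2 and from 0.992 to 1.024 on slide 1, so that contrast is also one between slides. The slope does not exclude a slight compression. A share of unresponsive cells stays open: for 454 genes that fell over 4-fold in replicate 1, the level left in replicate 2 exceeded that in replicate 1 by 0.052 to 0.19 of the 0h level between the quartiles, and the test needed a lower quartile above 0.1 or at most 0. An earlier stage of the same change stays open too, since the gap of replicate 2 correlated over genes with the 24h vs 8h change at -0.561 in ranks, but both share an array. With the change in replicate 2, where the shared array pushes the other way, it was -0.414, short of the bound of -0.5, and any smaller response would give the same sign. The replicates share a label and no biological difference between them is named, so none was tested.

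The third pattern is the opposite change at 24h of genes that the inhibitor had moved. The 0h arrays shared by both comparisons are argued against as the whole cause by 408 genes with opposite calls in 24h vs 2h, where independent lists would share 64.6. Loss of the inhibitor's action in the longer culture, with no part for the fusion, stays open. Of these 436 genes, 20.4% were called beyond the DMSO level at 24h (89 beyond, 2 short of it and 345 not called against DMSO), where the bounds written beforehand were at most 5 for it and more than 20 against it. That margin does not hold: with genes picked and called again, the percentage was 6.9 without 24h replicate 1, 7.2 without DMSO replicate 1 and 31.4 without 24h replicate 2. The median of 24h vs DMSO was 0.304 for the genes the inhibitor had lowered and -0.2 for those it had raised. An action of c-Raf on the genes that FGF receptors control is the other candidate explanation, and the values do not decide between them. An effect of 4OHT itself was not tested, since no cells with 4OHT and no fusion were analysed here.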

How the results depend on the processing

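Of 3420 re-tests of 250 named gene results, which do not include the samples as attached to the scanner files or a 2-fold minimum, 2716 kept their call and direction, 682 were weaker, 19 stronger and 3 reversed (Ppp1r3c at 4h, 0.024, and Pdgfra at 8h, 0.038, with normexp correction; Etv5 at 24h, -0.227 to 0.428 over the left-out arrays, reversed without 0h replicate 2). Counts of calls moved with the samples as attached to the scanner files, with the block, with median centring and with fewer arrays, and which of these moved a count most differed between comparisons. The cause was not tested. The order of values below is 0h vs DMSO, then times vs 0h, then vs 2h.

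With arrays grouped as attached to the scanner files, calls were 6 (0h vs DMSO), 7 (30m), 0 (1h), 560 (2h), 304 (4h), 388 (8h) and 331 (24h), 0, 5 and 3 for 4h, 8h and 24h vs 2h, and 252 for 24h vs DMSO. Rises then outnumbered falls, with 289 and 15 at 4h, 355 and 33 at 8h, 310 and 21 at 24h, and 237 and 15 for 24h vs DMSO. Genes with opposite calls were 0 and the time course test called 633. List medians were -0.169 for ERK feedback and ETS in 0h vs DMSO (camera adjusted p = 0.989), 0.309 for immediate early (camera adjusted p = 0.388) and 0.334 for ERK feedback and ETS (camera adjusted p = 0.787) at 1h, and -0.655 for naive pluripotency at 24h (camera adjusted p = 0.17). The formative and early epiblast median at 24h reversed to -0.266 (camera adjusted p = 0.505). On the 8 arrays where both records agree these medians were -0.779, 0.246, 0.130, -1.282 and 0.463, but those arrays are also part of the fit, and at 24h vs 0h they compare 1 array on each slide, so the last 2 of these medians also hold any slide difference.

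With the replicate block, calls were 2342 (0h vs DMSO), 3 (1h), 75 (2h), 2523 (4h), 3293 (8h), 6181 (24h), 88, 2895 and 6126 vs 2h, 4067 (24h vs DMSO), 1801 opposite and 7144 in the time course test. With the block and a 2-fold minimum they were 3 (1h), 49 (2h), 2434 (24h), 63 (4h vs 2h) and 2284 (24h vs 2h). With a 2-fold minimum alone they were 308, 289 (4h), 691 (8h), 2088 (24h), 506 and 1942 vs 2h, 1043 (24h vs DMSO) and 237 opposite.

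With median centring, calls were 261 (0h vs DMSO), 5 (2h), 104 (4h), 476 (8h), 2148 (24h), 2, 280 and 1887 vs 2h, 813 (24h vs DMSO), 216 opposite and 1671 in the time course test. With no filter on dim probes they were 340, 11 (2h), 273 (4h), 690 (8h), 0 (4h vs 2h), 528 (8h vs 2h) and 274 opposite, and the ERK feedback and ETS median at 1h was 0.25 (camera adjusted p = 0.47), against 0.216 (camera adjusted p = 0.181) with normexp. Calls in 4h vs 2h were 2 with normexp, quantile normalization or the filter on all 16 arrays, and 3 with trend and robust settings. In fits of only the 2 groups, calls were 0 (0h vs DMSO), 0 (2h), 6 (4h), 0 (8h), 1759 (24h), 0, 1 and 1536 vs 2h, and 185 (24h vs DMSO).

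With an estimated correlation, the medians -0.912 (ERK feedback and ETS, 0h vs DMSO, camera adjusted p = 0.708), 0.234 (immediate early, 1h, camera adjusted p = 0.788), 0.25 (ERK feedback and ETS, 1h, camera adjusted p = 0.93) and -2.144 (naive pluripotency, 24h, camera adjusted p = 0.788) were not called. Leaving out 1 array gave 72 to 195 calls in 0h vs DMSO, 0 to 21 at 30m, 0 to 9 at 1h, 2 to 25 at 2h, 41 to 572 at 4h, 152 to 1917 at 8h, 1859 to 3245 at 24h, 0 to 12, 118 to 1531 and 1837 to 3015 vs 2h, and 356 to 1938 in 24h vs DMSO. The same medians ran from -1.295 to -0.771, 0.192 to 0.225, 0.068 to 0.458 and -2.73 to -1.327, with -0.152 to 0.224 for primitive endoderm (reversed at -0.152 without 0h replicate 1 and -0.003 without 24h replicate 1) and 0.443 to 0.938 for formative and early epiblast genes at 24h.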

Other observations

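Beyond the developmental genes, single members of stress and signalling lists changed at 24h vs 0h, in both directions (limma, 2 arrays per group). Of the unfolded protein and ATF4 response list, 4 of 18 rose and 4 fell (10 and 5 with the replicate block). Ddit3, a stress transcription factor, rose by 2.52 ± 0.56 on the log2 scale, Ddit4 by 2.13 ± 0.45, Trib3 by 1.08 ± 0.28 and Xbp1 by 1.07 ± 0.19. Of 17 p53 targets 4 rose and 1 fell, with Perp up by 2.53 ± 0.33, Plk2 by 1.06 ± 0.18 and Mdm2 by 0.77 ± 0.19, and Sesn1 down by 1.03 ± 0.33. Hspa1a and Cryab rose by 1.58 ± 0.16 and 1.39 ± 0.31, the 2 called of 11 heat shock genes (3 higher and 1 lower with the block). Car9 and Adm, genes known from hypoxia, rose by 1.76 ± 0.33 and 1.39 ± 0.34, while the glucose transporter gene Slc2a3 and the hexokinase gene Hk1 fell by 1.57 ± 0.30 and 1.77 ± 0.39. None of these 4 lists shifted as a whole (camera adjusted p = 0.439, 0.104, 0.566 and 0.94).

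Interferon-response genes split at 24h, with 3 of 13 higher and 4 lower (camera adjusted p = 0.91): Bst2 rose by 2.10 ± 0.28 and Rsad2 at least 4.89-fold, while Oas1a fell by 2.99 ± 0.65 and Irf1 by 2.34 ± 0.57. Of 15 LIF and STAT3 targets 3 rose and 5 fell, with Junb up by 2.36 ± 0.53 (camera adjusted p = 0.595). Of 10 estrogen receptor targets, which bear on 4OHT as a ligand of that receptor, 3 rose and 3 fell: Nrip1 rose by 1.87 ± 0.23 and Greb1 by 0.93 ± 0.23, and Cxcl12 fell by 3.50 ± 0.77 (camera adjusted p = 0.9). Cholesterol synthesis genes stood at 3 higher and 1 lower of 20 (7 and 2 with the block), with Msmo1 up by 1.11 ± 0.23 and Mvk down by 0.54 ± 0.14 (camera adjusted p = 0.058). Rrp12 and Odc1 rose by 0.78 ± 0.20 and 0.59 ± 0.17, the 2 called of 22 ribosome biogenesis genes (camera adjusted p = 0.092). With the block 11 were higher and the list was called (camera adjusted p = 0.0102, against 0.93 with an estimated correlation and no block). Of 16 germ cell and imprinted genes 4 rose and 3 fell (9 and 5 with the block), among them Dlk1 (1.74 ± 0.17), Mael (1.38 ± 0.33), Peg3 (-2.24 ± 0.35) and Prdm1 (-1.99 ± 0.43; camera adjusted p = 0.391). Of 7 two-cell-like genes 1 fell (2 with the block), Zfp352 by 0.76 ± 0.21. Of 15 housekeeping genes, Hprt rose by 1.38 ± 0.20 and Sdha fell by 0.34 ± 0.11 (2 higher and 1 lower with the block), with a list median of -0.01.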
